A study of Mus musculus with 2 samples.

How the data were processed

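Total RNA of embryonic day 15.5 mouse hindbrain was measured in 2 libraries, which the labels give as biological replicates 1 and 2 of 1 group. Per the labels, RNA was extracted with a mirVana kit and the libraries were made from 10 ng of RNA with ERCC spike-ins. For each library a gene table and a transcript table were used. Per the file headers and accompanying notes, values were made on mm10 with GENCODE M4 from alignments to the transcriptome of 1 library each, without pooling. The aligner, the quantifier and whether counting used strand are not given in the sources used here. The column names are those that RSEM writes with its posterior option.

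The deposited estimated counts are reads per gene or transcript, need not be whole, and are not normalized, per the file headers. The deposited TPM values are scaled over every feature in a file, spike-ins included. The deposited FPKM values, per the file headers, are scaled by effective length and by the reads assigned in the library, and served only as an alternative for detection. The deposited bounds of the TPM interval and the posterior values, a signal with its own spread per the file headers, served as alternatives and to mark uncertain genes. The deposited percent of each gene's TPM held by a transcript was the authors' own; shares printed here were computed from the transcript TPM. Effective length was 99 nt below transcript length for 100% of transcripts, so the TPM of short transcripts depends most on that offset.

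The gene tables held 43346 genes, 97 spike-in features and 26248 features with a numeric identifier, and 103639 transcripts of genes stood in the transcript tables. Gene symbols, types and positions came from GENCODE M21 on GRCm38, the same assembly as mm10, by identifier without version. Of the identifiers 42462 matched and 884 did not, and the unmatched held 0.200% of gene counts. Spike-ins held 2.86% of all counts in replicate 1 and 3.09% in replicate 2. Spike-ins and numeric identifiers stayed out of library sizes and of every list. A coding gene at 0.9 to 1.1 TPM had a median of 53.0 counts in replicate 1 and 60 in replicate 2.

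Detection was 1 TPM or more in both libraries. A list's level is the median over genes of the mean TPM, its SD is that of the 2 library medians, and its percentile is that among 10000 random lists of nuclear protein-coding genes of the same size. Counts were scaled with TMM in edgeR 4.0.16 under R 4.3.3. The log2 ratio of replicate 2 over replicate 1 used a prior count of 0.5 and genes with a mean count of 20 or more. A list's median log2 ratio was set against 10000 random lists of the same size matched on mean expression in 20 bins, and called apart outside the 2.5th to 97.5th percentile. Lists with fewer than 5 genes compared were not tested, which left out the inner ear, Y-linked and X inactivation lists among 38. The list of genes chosen for splicing was at first left out of the count of lists apart and was put back, as planned, after its value had been seen, so the count without it is given too. Poisson sampling alone was drawn 100 times. For a count of 0, the floor was 3 counts in that library. The biological coefficient of variation came from an intercept-only dispersion estimate in edgeR on estimated counts rounded to whole numbers, after its filter on low counts. With 1 library per pool and 1 group, no p-value was computed. The leading transcript is that of highest TPM, in genes at 5 TPM or more in both libraries with several annotated transcripts.

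The groups, results, alternatives, gene lists and the rule for naming genes were chosen before the data were examined. Named were every Hox gene detected in both libraries, and the highest of groups 6 to 13. In each list the 4 members of highest mean TPM were named, and in lists with under 50% detected also the highest member not detected. Further named were the 10 nuclear coding and 5 noncoding genes of highest TPM, and 8 genes per direction of largest ratio at a mean count of 100 or more. Of the splicing list, genes with a leading share under 50% or a leader that differed were named, and the 4 highest shares. Some genes that this rule takes are not reported here. Of 563 genes in the fixed lists, 7 were not matched, namely Lhfpl3, Ahsp, Rmst, Sox2ot, Snhg1, Dancr and Dlx6os1, and were left out.

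Alternatives were TPM minimums of 0.5 and 2, posterior mean TPM, TPM over nuclear coding genes, an FPKM minimum of 1, the lower TPM bound and each library alone. For ratios they were DESeq2 1.42.0 size factors, library totals, spike-in totals, a mean count minimum of 100 or none, and TPM ratios with pseudocounts of 1 and 0.1. The dispersion was also estimated without a filter, on coding genes alone and with DESeq2 size factors. Leading transcripts were also counted at gene minimums of 1 and 20 TPM, on posterior TPM and for coding genes alone.

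The comparison of replicate 2 with replicate 1 was tested on simulated data over 17048 genes. Of 200 genes changed 4-fold, 195 were found over 2-fold apart, as were 39 of 16848 unchanged genes. Of 20 lists shifted by 0.5 on the log2 scale 20 were called apart, and 1 of 20 unshifted lists. Simulated genes were drawn independently, all with the common coefficient of variation estimated here. Lists of genes regulated together, the larger spread at low abundance and shifts under 0.5 were therefore not covered. Simulated coefficients of variation of 0.05, 0.1 and 0.2 over 17930 genes were recovered as 0.0498, 0.0991 and 0.200. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for the rest.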

Results

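Total RNA was sequenced from the hindbrain of mouse embryos of strain B6NCrl at embryonic day 15.5. The hindbrain is the most caudal part of the brain and gives rise to the medulla, the pons and the cerebellum. The series held 1 group of 2 biological replicates, each a pool of both sexes. Replicate 1 came from 78 embryos and replicate 2 from 62. Each library started from 10 ng of RNA longer than 200 nt with synthetic spike-in RNAs added. The deposited gene tables held 40020322 estimated counts in genes for replicate 1 and 43263959 for replicate 2. With a single tissue and stage there was no contrast between conditions. The questions addressed were therefore which genes and cell types the tissue expressed, at which level, and how far the 2 pools differed. Levels are given in TPM, a length-corrected relative abundance, as mean ± SD with n = 2 throughout. Ratios between the libraries are replicate 2 over replicate 1 after scaling, with 95% exact (Clopper-Pearson) intervals. The tables carry no molecular identifiers, so intervals and detection floors cover counting error only.

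Nuclear protein-coding genes took 94.2 ± 0.464% of the counts in genes. Of the nuclear genes that code for protein, Tuba1a, the neuronal alpha-tubulin on chromosome 15, was highest at 13468 ± 585 TPM. Next came the alpha-globin gene Hba-a2 at 6319 ± 1039 TPM and Nnat, an imprinted neuronal gene, at 5703 ± 296 TPM. Actb stood at 4826 ± 120.3 TPM and Stmn1, a microtubule regulator of growing neurons, at 4778 ± 139.6 TPM. The ferritin light chain gene Ftl1 followed at 4600.2 ± 90.8 TPM. Tmsb4x and Tmsb10, which encode actin-binding thymosins, had 4232 ± 278 and 3899.6 ± 51.3 TPM. The polyubiquitin gene Ubb had 3458 ± 11.4 TPM and Ppia 3399 ± 128 TPM. Among noncoding genes Rn7s2 and Rn7s1, which encode the RNA of the signal recognition particle, led at 16817 ± 2057 and 16816 ± 2058 TPM. They are near-identical copies whose reads were shared, so the split between them is uncertain. Malat1, a nuclear long noncoding RNA, had 6597 ± 931 TPM. The pseudogene Gm28437 on chromosome 1 had 8434 ± 321 TPM and may hold reads of the mitochondrial genome. The small gene Gm22133 at 4093 ± 40.4 TPM lies inside Ftl1, so its value is uncertain too. At 1 TPM or more in both libraries, 15436 genes were detected, among them 13542 nuclear protein-coding genes, which are 63.1% of the 21461 in the tables. A further 580 genes reached that level in replicate 1 alone and 499 in replicate 2 alone.

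Hox genes, the transcription factor genes that mark position along the body axis, were expressed mainly in paralogue groups 2 to 8. Of the 15 genes in groups 1 to 5, 13 were detected in both libraries, and their median was 12.9 ± 0.431 TPM. Groups 6 to 13 had 8 of 24 genes detected and a median of 0.0725 ± 0.0707 TPM. Among random lists of nuclear protein-coding genes of the same size, the first median lay at the 81.3th percentile and the second at the 0.150th. Hoxb5 was highest at 103 ± 15 TPM, followed by Hoxa5 at 88.5 ± 6.65, Hoxc4 at 48.5 ± 4.29 and Hoxd3 at 40.6 ± 1.08 TPM. Lower values were measured for Hoxb2 at 24.0 ± 3.62, Hoxa2 at 20.5 ± 2.61, Hoxc5 at 16.9 ± 1.23 and Hoxa3 at 12.9 ± 0.431 TPM. Hoxb3 had 10.3 ± 0.113, Hoxa4 9.17 ± 0.933, Hoxb4 2.92 ± 0.177 and Hoxd4 2.42 ± 0.318 TPM. Hoxb1 and Hoxd1, named after their values were seen, did not reach the minimum in both libraries, with means of 0.33 ± 0.127 and 1.43 ± 0.707 TPM. In the more caudal groups Hoxb6 was highest at 47.9 ± 8.68 TPM. It was followed by Hoxb7 at 24.2 ± 4.17, Hoxb8 at 17.9 ± 4.62, Hoxa7 at 14.4 ± 9.10 and Hoxa6 at 9.60 ± 1.79 TPM. Hoxc6 had 8.24 ± 3.31, Hoxc8 7.65 ± 8.16 and Hoxb9 7.22 ± 7.81 TPM, the last 2 with an SD above the mean. Hoxa9 was the highest gene that missed the minimum, with 0.45 TPM in replicate 1 and 2.78 TPM in replicate 2. Summed over its genes, group 5 reached 208 ± 22.8 TPM, group 8 26.4 ± 13.1 TPM and group 10 0.28 ± 0.0566 TPM. For a coding gene of median length, 3 counts correspond to 0.047 TPM in replicate 1 and 0.0444 TPM in replicate 2, so genes listed at 0 were not detectable at this depth.

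By cluster on GRCm38, Hoxb (chromosome 11, 96194316 to 96368256) summed to 237 ± 43.8 TPM and Hoxa (chromosome 6, 52155590 to 52260880) to 158 ± 23.5 TPM. Hoxc (chromosome 15, 102921103 to 103036852) reached 81.5 ± 17.2 TPM and Hoxd (chromosome 2, 74668310 to 74765142) 45.3 ± 1.77 TPM. Annotated spans overlap inside the clusters. Hoxd3 spans Hoxd4, Hoxa3 spans Hoxa4, Hoxa5 and Hoxa6, and Hoxc5 spans Hoxc6 and Hoxc8. The genes of a cluster lie on the same strand, so counting by strand could not part such neighbours. The split between them is therefore uncertain.

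**Figure D1:**
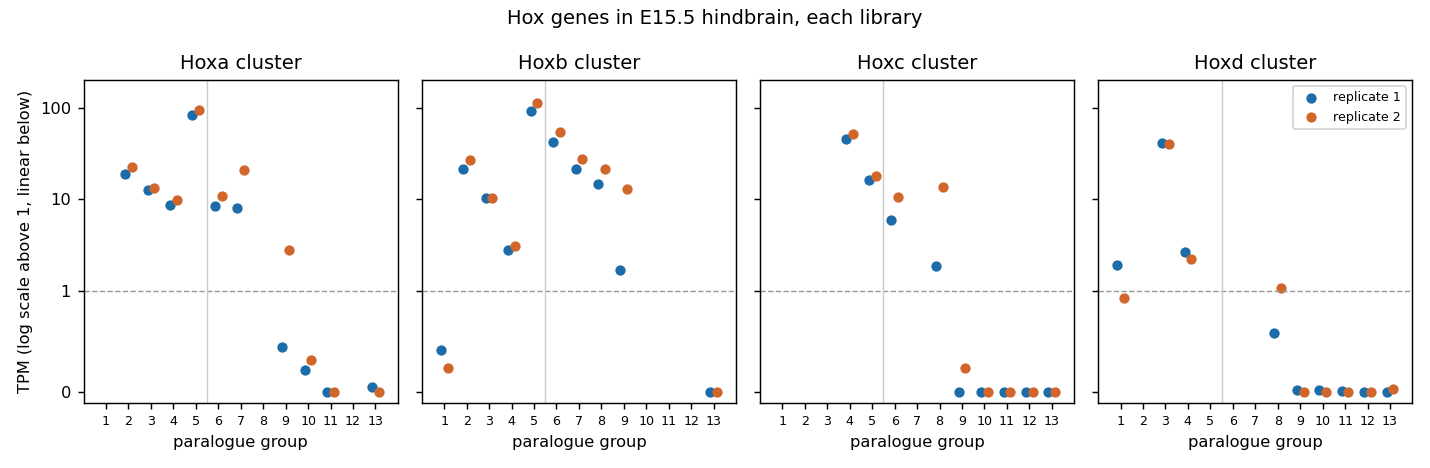
TPM of Hox genes (vertical axis, log scale above 1 and linear below) against its paralogue group (horizontal axis), with 1 panel per cluster and 1 point per library. Hoxb5 and Hoxa5 stand highest, and Hoxb9 and Hoxc8 lie well above replicate 1 in replicate 2; the dashed line marks 1 TPM and the grey line parts groups 1 to 5 from 6 to 13.

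Transcription factors of the forebrain were mostly low. Of 26 such genes, 6 were detected in both libraries, with a median of 0.970 ± 0.453 TPM, at the 5.87th percentile of random lists. That count rested on replicate 1, since 7 of the genes reached 1 TPM in replicate 1 and 14 in replicate 2. At a minimum of 0.5 TPM it was 11. Neurod6 at 29.5 ± 8.29 and Neurod2 at 19.9 ± 4.50 TPM, both genes of maturing excitatory neurons, were highest. Otp had 5.17 ± 0.325 and Bhlhe22 3.42 ± 0.445 TPM. Dlx1, a gene of forebrain interneuron precursors, was the highest that missed the minimum, with 0.3 TPM in replicate 1 and 5.52 TPM in replicate 2. Of 13 midbrain genes 8 were detected, with a median of 1.5 ± 0.332 TPM, and 5 at a minimum of 2 TPM or of 1 FPKM. The highest were Pou4f1 at 40.8 ± 9.14, Otx2 at 22.7 ± 7.71, Nr4a2 at 16.6 ± 4.67 and Sox14 at 10.6 ± 2.35 TPM. Several of these are also made outside the midbrain, Pou4f1 in sensory and precerebellar neurons and Otx2 in choroid plexus. Genes of the isthmus, the border between midbrain and hindbrain, and of the early cerebellum were detected in 10 of 13 cases, with a median of 9.84 ± 0.827 TPM. Zic4 led at 45.6 ± 5.5 TPM, followed by Gbx2 at 32.8 ± 2.64, Irx2 at 29.4 ± 1.48 and Pax8 at 16.7 ± 3.15 TPM.

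Most genes listed for the main neuron lineages of the cerebellum were detected. Some of them, such as Barhl1, Lhx1 and Lhx5, stand in other lists too, so these levels are not those of cerebellar cells alone. Of 21 genes of the rhombic lip and the granule cells it produces, 20 were detected, with a median of 23.9 ± 0.240 TPM at the 98.3th percentile. Meis1 had 136 ± 11.8, Mab21l1 126 ± 2.81, Mycn 54.0 ± 4.86 and Barhl1 41.8 ± 9.46 TPM. Of 23 genes of the Purkinje cell lineage 22 were detected, with a median of 19 ± 4.03 TPM at the 96.4th percentile. Pcp4, a calmodulin-binding protein of Purkinje cells, led at 356 ± 17.4 TPM, and Ebf1, Dab1 and Foxp1 had 96.1 ± 22.4, 68.4 ± 8.94 and 54.4 ± 7.28 TPM. Genes of precerebellar and other glutamatergic hindbrain neurons were detected in 13 of 14 cases, at a median of 25.8 ± 5.31 TPM. In that list Slc17a6, a vesicular glutamate transporter, had 74.8 ± 3.55 TPM and Nfib 57.2 ± 1.77 TPM. Its next members, Barhl1 and Pou4f1, are shared with lists above.

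Among the transmitter lists, genes of inhibitory neurons had a higher median than those of monoamine and motor neurons. All 16 genes of GABA and glycine neurons were detected, at a median of 36.5 ± 2.89 TPM and the 99.7th percentile. The peptide genes Sst and Npy had 272 ± 3.72 and 138 ± 3.40 TPM. Gad1, which makes GABA, had 82.7 ± 0.566 TPM. All 12 serotonergic genes were detected at a median of 5.68 ± 0.435 TPM, with Gata3 at 24.6 ± 1.84, Slc18a2 at 14.3 ± 0.721, Gata2 at 9.60 ± 0.184 and Ddc at 7.33 ± 0.283 TPM. Noradrenergic and visceral neuron genes were detected in 8 of 10 cases at a median of 6.98 ± 0.859 TPM. Besides Slc18a2, Tlx3 had 13.3 ± 1.88 and Ret 9.41 ± 0.255 TPM. For cholinergic and motor neurons 10 of 12 genes were detected at a median of 4.86 ± 0.636 TPM. Prph, an intermediate filament of peripheral and motor neurons, had 57.2 ± 17.8 TPM. Slc18a3 had 15.2 ± 0.403, Isl1 14.1 ± 3.37 and Slit3 10.2 ± 0.325 TPM.

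Genes of postmitotic neurons had the highest median of any nuclear list, 480.0 ± 30.1 TPM over 22 genes, all detected. After Tuba1a and Stmn1, its leaders were Tubb3 at 1426 ± 26.9 and Stmn3 at 1260.0 ± 17.2 TPM. Synaptic genes were detected in 24 of 24 cases at a median of 46.5 ± 2.26 TPM. Vamp2, Snap25, Syp and Cplx1 had 303 ± 70.2, 201 ± 31.3, 158 ± 2.04 and 143 ± 10.4 TPM. Radial glia and progenitor genes were detected in 19 of 20 cases at a median of 18.1 ± 0.173 TPM. Fabp7, a lipid-binding protein of radial glia, led at 1780.3 ± 48.5 TPM, before Vim at 402 ± 25.7, Slc1a3 at 171 ± 17.8 and Hes5 at 142 ± 20.0 TPM. All 25 cell cycle genes were detected at a median of 27.8 ± 2.42 TPM, with Pcna at 94.1 ± 4.49, Ube2c at 74.4 ± 16, Cdk1 at 70.7 ± 11.9 and Mcm6 at 60.1 ± 0.368 TPM. Replication-dependent histone genes had a median of 5.73 ± 1.77 TPM with 12 of 16 detected. Their highest members were Hist1h2ap at 615 ± 75.8 and Hist1h4d at 121 ± 31.1 TPM, followed by Hist1h2ae at 36.4 ± 13.1 and Hist1h2bc at 32.7 ± 6.41 TPM. These are near-identical copies and their values are uncertain. Genes that read out hedgehog, Wnt and Notch signalling were all detected, 16 of 16, at a median of 10.7 ± 1.48 TPM. Besides Hes5, the highest were Nkd1 at 26 ± 3.34, Hey1 at 22.1 ± 1.56 and Dll3 at 18.4 ± 4.91 TPM.

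Glial lists differed in level. All 15 astrocyte genes were detected at a median of 57.2 ± 4.30 TPM, with Sparcl1 at 253 ± 10.7, Gja1 at 89.6 ± 13.0 and Clu at 66.8 ± 0.580 TPM besides Slc1a3. Slc1a3 stands in the radial glia list too, and Nfib, whose value is the median, in the precerebellar list. The level of this list is therefore not that of astrocytes alone. All 9 matched genes of oligodendrocyte precursors were detected, at a lower median of 6.63 ± 0.233 TPM. Olig1 had 103 ± 9.33, Sox8 17.1 ± 3.54, Olig2 13.3 ± 0.297 and Pdgfra 12.6 ± 0.693 TPM. Of 10 myelin genes 7 were detected at a median of 3.67 ± 0.0849 TPM. Cldn11, which meningeal cells also make, had 52.9 ± 11.2 TPM, and Cnp and Mbp had 48.8 ± 0.962 and 30.6 ± 1.99 TPM. Microglia and macrophage genes were detected in 15 of 16 cases at a median of 8.57 ± 0.527 TPM. The complement gene C1qb had 39.8 ± 7.55 TPM, Lyz2 28.0 ± 6.34, Tyrobp 27.3 ± 5.57 and C1qa 27.0 ± 3.02 TPM.

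RNA of vessels, blood, meninges and choroid plexus was present beside that of neural cells. All 16 genes of endothelium and pericytes were detected at a median of 13.7 ± 0.870 TPM, led by Vtn at 130.1 ± 3.92, Cldn5 at 91.6 ± 3.33, Slc2a1 at 76.4 ± 1.35 and Esam at 36.5 ± 0.127 TPM. Erythroid genes were detected in 10 of 13 cases at a median of 31.4 ± 6.14 TPM. After Hba-a2 the adult globin genes Hbb-bs, Hba-a1 and Hbb-bt had 3269 ± 659, 2359 ± 315 and 2093 ± 378 TPM, and Hba-a1 and Hba-a2 are near-identical copies. Globin genes took 0.446 ± 0.0813% of the counts in genes. All 15 genes of meninges and fibroblasts were detected at a median of 44.8 ± 7.33 TPM, with Ptgds at 659 ± 188, Col3a1 at 188 ± 23.4, Igf2 at 129.7 ± 22.9 and Col1a2 at 107 ± 16.6 TPM. Choroid plexus genes were detected in 13 of 14 cases at a median of 15.3 ± 3.31 TPM. Ttr, the transthyretin gene that marks choroid epithelium, had 1025 ± 223 TPM, Enpp2 61.3 ± 3.80, Folr1 32.6 ± 12.4 and Msx1 25.4 ± 6.03 TPM. Genes of peripheral nerve and sensory ganglia were detected in 15 of 17 cases at a median of 10.1 ± 2.22 TPM. Besides Prph and Pou4f1, the highest were Ntrk2 at 47.0 ± 3.59 and Ngfr at 35.3 ± 1.41 TPM.

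Lists of skeletal muscle, cartilage and bone, and inner ear had medians near or below the minimum of 1 TPM. Of 14 skeletal muscle genes 6 were detected, with a median of 1.12 ± 0.414 TPM, and 3 at a minimum of 2 TPM. Acta1 had 7.5 ± 1.32, Mylpf 3.75 ± 0.0990, Actc1 3.13 ± 2.81 and Tnnt3 2.77 ± 0.212 TPM. Tnnc2, the highest that missed the minimum, had 1.93 TPM in replicate 1 and 0.79 TPM in replicate 2. Cartilage and bone genes were detected in 5 of 13 cases at a median of 0.545 ± 0.00707 TPM. Sox9, also a radial glia gene, had 44.7 ± 6.88 TPM, Col2a1 24.1 ± 4.55, Col11a1 9.96 ± 0.460 and Cnmd 4.18 ± 0.587 TPM. Matn1 missed the minimum at 0.945 ± 0.7 TPM. Inner ear genes were detected in 2 of 10 cases at a median of 0.217 ± 0.0141 TPM. The detected members, Myo7a at 14.3 ± 1.61 and Atoh1 at 12.8 ± 2.18 TPM, are also made elsewhere, Atoh1 in the rhombic lip. Pou4f3 had 5.06 TPM in replicate 1 and 0.71 TPM in replicate 2.

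**Figure D2:**
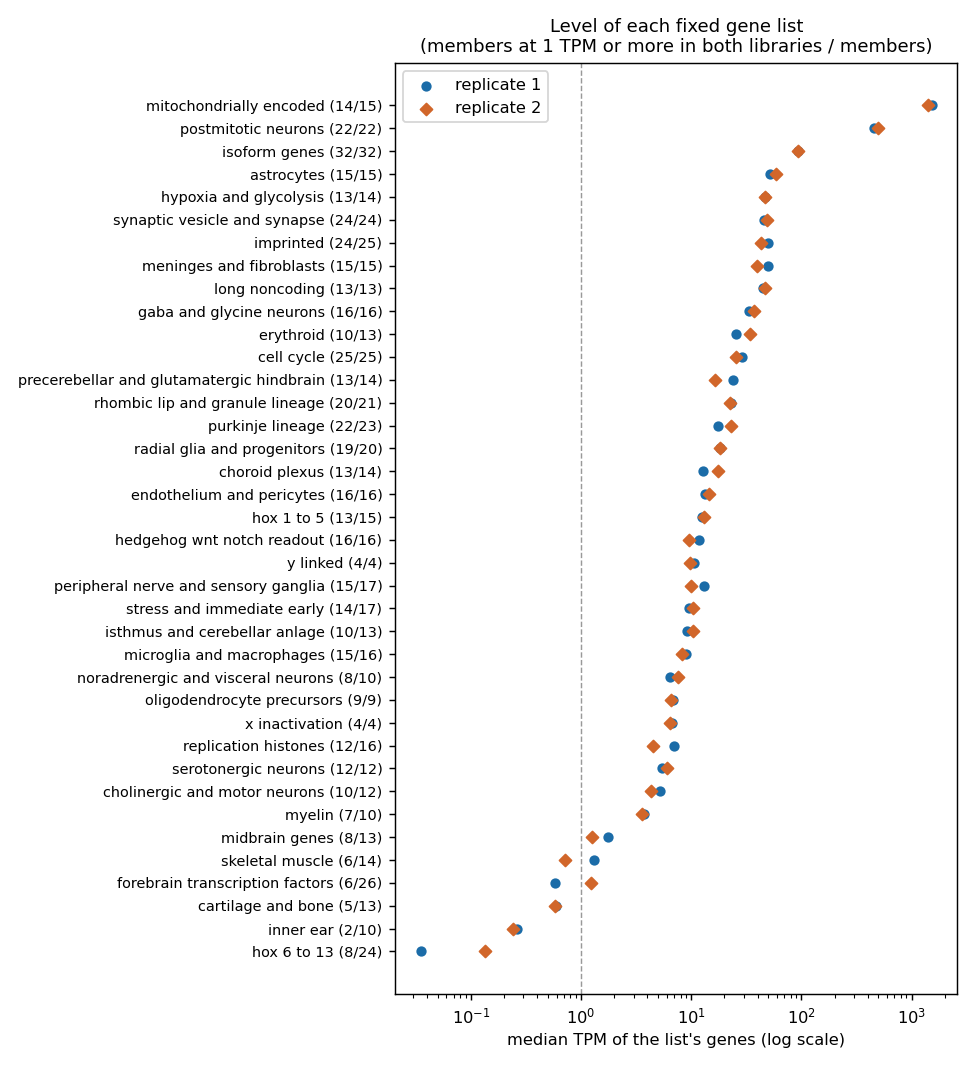
Median TPM of each fixed gene list (horizontal axis, log scale) in each library, with the number of members at 1 TPM or more in both libraries over the number matched. Postmitotic neuron genes stand at 480.0 ± 30.1 TPM and Hox groups 6 to 13 at 0.0725 ± 0.0707 TPM.

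Both sexes were seen in each pool, as the labels state. The Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty had 30.5 ± 0.615, 13.6 ± 1.3, 6.75 ± 0.113 and 6.32 ± 0.346 TPM. Xist, the RNA that silences an X chromosome in females, had 16.2 ± 0.679 TPM, and Ftx, Tsix and Jpx had 6.67 ± 0.134, 6.46 ± 0.389 and 4.97 ± 0.594 TPM. Tsix is antisense to Xist, so its value is uncertain without a stated strand. The medians were 10.2 ± 0.569 TPM for the Y-linked list and 6.56 ± 0.127 TPM for the X inactivation list. Imprinted genes were detected in 24 of 25 cases at a median of 46.1 ± 4.64 TPM. After Nnat, Meg3 had 1802 ± 102, Gnas 1310.3 ± 38.9 and Ndn 1105 ± 50.9 TPM. All 13 matched long noncoding genes were detected at a median of 40.3 ± 1.74 TPM, with Snhg11 at 635 ± 103 and Gas5 at 322 ± 12.7 TPM below Malat1 and Meg3. Genes encoded on the mitochondrial chromosome took 1.68 ± 0.132% of the counts and were detected in 14 of 15 cases at a median of 1431 ± 87.0 TPM. The highest were mt-Atp6 at 7438 ± 143, mt-Atp8 at 5708 ± 343, mt-Rnr2 at 3589.5 ± 977 and mt-Cytb at 3449 ± 221 TPM. Genes of hypoxia and glycolysis had a median of 46.9 ± 0.453 TPM with 13 of 14 detected, led by Eno1 at 923 ± 24.0, Ldha at 572 ± 14.2, Aldoa at 569 ± 12.3 and Pfkp at 360.4 ± 18.9 TPM. Stress and immediate early genes had a median of 10.1 ± 0.516 TPM with 14 of 17 detected. Dnajb1 had 63.4 ± 1.59, Jun 49.4 ± 1.27, Btg2 31.9 ± 10.3 and Dusp1 25.1 ± 4.08 TPM. The lists were chosen for this tissue, so high percentiles follow partly from that choice.

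The 2 pools were close for most genes. Over 17048 genes with a mean estimated count of 20 or more, the log2 ratio after scaling had an SD of 0.40 across genes. Across the 16001 genes at a mean of 1 TPM or more, Pearson's r of log2(TPM + 1) was 0.987 and Spearman's rho 0.988, across genes, which are not independent replicates. Their counts gave a chi-square of 12.4 per degree of freedom over genes, so they were not 1 library deposited again and were counted as 2 replicates. The common biological coefficient of variation (BCV), the spread between the pools beyond counting error relative to the mean, was 0.0892 over 17930 genes in edgeR. Among 4 bins of abundance the trended value went from 0.199 in the lowest to 0.0591 in the highest. Directions below are relative to the median gene. Scaling by spike-in totals instead would move that gene by -0.11 on the log2 scale.

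Several whole gene lists differed between the pools. Of 35 lists with at least 5 genes compared, 21 had a median log2 ratio outside the central 95% of random lists matched on expression, where chance gives 1.75. Genes of a list that are regulated together stand apart more easily than independent ones, and with 1 library per pool the comparison has no replicate check. Without the list of genes chosen for splicing, an alternative chosen after its value was seen, the count was 20 of 34. Of the 21 lists, 11 were higher in replicate 2 and 10 lower. Signs held under each scaling tried except that of the list of 32 spliced neural genes, whose median of 0.06 became -0.05 under spike-in totals. The largest positive median was that of Hox groups 6 to 13 at 0.81, with 10 of 10 genes higher. Forebrain transcription factors followed at 0.74, with 16 of 20 higher, among them Neurod6 at a ratio of 1.46 (1.36 to 1.57). Choroid plexus genes had 0.31 with 13 of 14 higher. Ttr had a ratio of 1.33 (1.31 to 1.36), while Otx2, also in the midbrain list, had 0.561 (0.513 to 0.612). The Purkinje lineage had 0.26 with 20 of 23 higher, and cartilage and bone 0.28 with 8 of 11 higher. Among the 3 lower Purkinje lineage genes, Neurog1 had a ratio of 0.0928 (0.0686 to 0.123). Neurog2, named after its value was seen, had 0.373 (0.326 to 0.426). Smaller positive medians were 0.15 for the isthmus list, 0.14 for GABA and glycine neurons, 0.13 for synaptic genes, 0.12 for Hox groups 1 to 5 and 0.12 for the rhombic lip list. Under spike-in totals these became 0.03, 0.03, 0.02, 0.01 and 0.00 in the same order, so they lay near 0 under that scaling. The rhombic lip list had a mean of 0.00 and a ratio of summed counts of 0.978 (0.966 to 0.990), on the lower side, and the isthmus list a mean of 0.01. In the isthmus list 8 genes were higher and 4 lower. Among the lower were En1 at 0.465 (0.392 to 0.551) and En2 at 0.439 (0.301 to 0.632), named after their values were seen.

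On the lower side, all 25 cell cycle genes were lower in replicate 2, with a median of -0.28 and Ube2c at a ratio of 0.721 (0.673 to 0.771). Replication histone genes had a median of -0.45 with 10 of 11 lower. Meninges and fibroblasts had -0.36 with 14 of 15 lower, where Ptgds had 0.649 (0.633 to 0.666). Microglia and macrophage genes had -0.32 with 15 of 16 lower, where C1qb had 0.746 (0.684 to 0.814). Peripheral nerve and sensory ganglia had -0.45 with 14 of 17 lower. Cholinergic and motor neurons had -0.44 with 8 of 11 lower, and Prph, which both lists hold, had 0.625 (0.591 to 0.662). Midbrain genes had -0.47 with 7 of 12 lower, and Nr4a2 went the other way at 1.35 (1.2 to 1.5). Skeletal muscle genes had -0.61 with 8 of 9 lower. Erythroid genes had -0.31 with 6 of 11 lower, but their mean log2 ratio was 0.04. Mitochondrially encoded genes had -0.08 with 10 of 15 lower, but a mean of 0.53. With mt-Nd4l, at 0 counts in replicate 1, set to its bound the median stayed at -0.08 and the mean was 0.35.

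The remaining 14 medians lay inside the range of random lists. These were 0.11 for oligodendrocyte precursors, 0.10 for noradrenergic and visceral neurons, 0.07 for the signalling readout, 0.06 for serotonergic neurons and 0.05 for postmitotic neurons. Precerebellar and glutamatergic neurons, stress genes, endothelium, long noncoding genes and astrocytes had 0.04, 0.04, 0.02, 0.01 and 0.00. Myelin, radial glia, imprinted and glycolysis genes had -0.01, -0.04, -0.04 and -0.05. Of these 14, 11 had the other sign under another scaling by construction, since a scaling moves all genes alike and these medians lie near 0. The median and mean differed in sign for 6, namely precerebellar, myelin, astrocyte, long noncoding, stress and signalling genes.

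**Figure D3:**
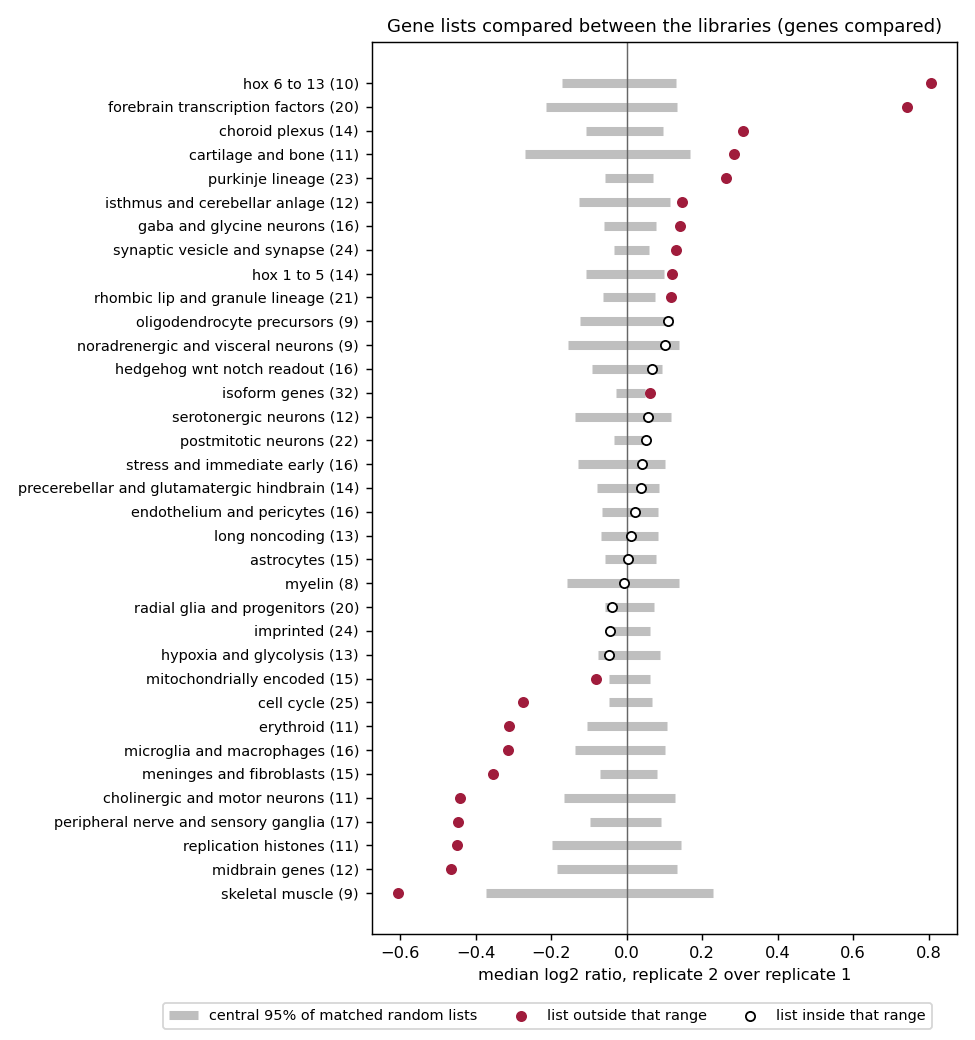
Median log2 ratio of replicate 2 over replicate 1 (horizontal axis) for each of 35 gene lists, with the number of genes compared in brackets. Grey bars span the central 95% of 10000 matched random lists, and the 21 filled points lie outside them, from skeletal muscle at -0.61 to Hox groups 6 to 13 at 0.81.

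Genes with large ratios between the pools included the transcription factor genes Dlx1, Hoxb9, Dbx1 and Neurog1 as well as pseudogenes. At a mean count of 100 or more, 60 of 13844 genes were over 2-fold apart, 17 higher in replicate 2 and 43 lower, where Poisson sampling alone gave 0 in each of 100 draws. Of the 60, 44 were nuclear protein-coding genes and 7 pseudogenes. At a mean count of 20 or more the number was 323 of 17048, 96 higher and 227 lower, against 20.0 on average from Poisson sampling. It was 84 on TPM with a pseudocount of 1, and 4943 with no minimum. Dlx1 on chromosome 2 (71528113 to 71533981) had a ratio of 21.8 (12.5 to 43.4), from 12.2 and 287 counts. Hoxb9 had 7.36 (6.02 to 9.09), Hoxc8 7.02 (5.61 to 8.87) and Hoxa7 2.53 (2.18 to 2.91). Tbr1, which specifies cortical projection neurons, had 3.22 (2.49 to 4.19). The pseudogene Gm15725 had 2.84 (2.18 to 3.69). On the other side Dbx1, a progenitor gene of the neural tube on chromosome 7 (49631499 to 49636849), was 16.2-fold lower in replicate 2 (13.9 to 19), at 51.8 against 3.27 TPM. Tfap2d was 11.5-fold lower (9.33 to 14.4) and the proneural gene Neurog1 10.8-fold lower (8.12 to 14.6). Pou4f3, a hair cell and sensory neuron gene, was 7.27-fold lower (5.28 to 10.2), Bhlhe23 7.25-fold (5.17 to 10.4), Tal2, a midbrain gene, 6.90-fold (5.13 to 9.47) and Neurod4 6.0-fold (4.83 to 7.53). At 0 counts in a library, mt-Nd4l was at least 126-fold higher in replicate 2 and the pseudogene Gm4294 at least 94.9-fold lower, each against 3 counts in the library at 0 and leaving out the counting error of the other library. The exact intervals, which include it, had bounds of 102-fold and 76.7-fold. Both share sequence with other genes, and the deposited TPM interval of mt-Nd4l in replicate 1 reached 293 TPM and that of Gm4294 in replicate 2 reached 209 TPM, so their ratios are uncertain.

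**Figure D4:**
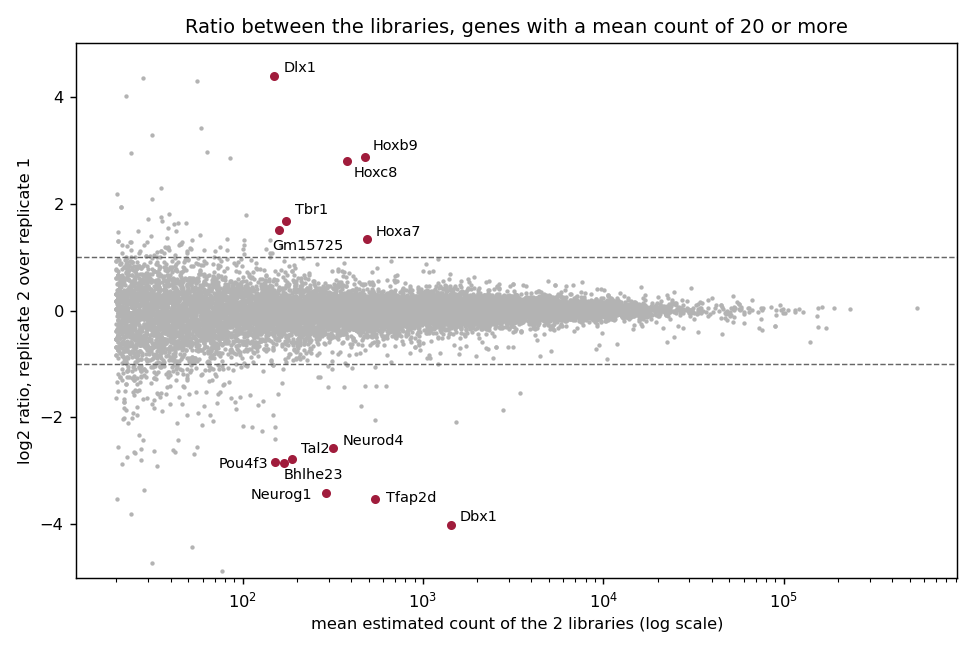
Log2 ratio of replicate 2 over replicate 1 (vertical axis) against the mean estimated count (horizontal axis, log scale) for 17048 genes, 1 point per gene. The points named are genes with large ratios at a mean count of 100 or more, dashed lines mark 2-fold, and mt-Nd4l and Gm4294 fall outside the axis.

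Transcript tables showed that most genes kept the same leading transcript, the transcript of highest TPM, in both pools. It differed for 536 of 8395 genes at 5 TPM or more with several annotated transcripts, which is 6.38%, for 845 of 10400 at a minimum of 1 TPM and for 268 of 5114 at 20 TPM. The leading transcript held a median of 67.5% of its gene, and 34.3% where it differed between the pools. Among 32 neural genes chosen for known splicing, all detected at a median of 91.8 ± 0.053 TPM, the highest were Mapt at 789.8 ± 74.0, Pkm at 765 ± 42.4, Cdc42 at 752 ± 10.3 and Ncam1 at 344 ± 31.1 TPM. Of the 32, 30 had the same leader, and in 17 it held less than 50% of the gene. Leading shares were 23.0 ± 9.66% for Dnm1, 32.5 ± 4.74% for Ptbp1, 25.5 ± 0.558% for Ank2, 26 ± 1.40% for Ank3, 26.4 ± 2.45% for Nrxn3 and 29.6 ± 9.27% for Grin1. In Dnm1 and Ptbp1 the leader differed. Mbp, Nfasc, Map2 and Dab1 had 32.5 ± 6.92, 34.1 ± 0.486, 37.7 ± 1.46 and 37.7 ± 4.71%. Dlg4 and Gria2 had 40.9 ± 6.47 and 41.4 ± 0.065%. The tau gene Mapt had 46.1 ± 0.890%, Dclk1 47.5 ± 1.23% and Agrn 47.7 ± 1.24%. In Gria2 and Agrn the leader was annotated as a transcript with a retained intron, and in Dab1 as a target of nonsense-mediated decay. The highest leading shares were those of Srrm4, a neuronal splicing factor, at 98.0 ± 0.180%, Snap25 at 93.8 ± 0.169% and Rbfox1 at 87.0 ± 0.367%, besides Ptbp2, which has a single annotated transcript in the tables.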

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

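Features with a numeric identifier, 26248 in each gene table, were outside every comparison and held 23.1 estimated counts in replicate 1 and 12 in replicate 2. Both sums lie above the 3 counts that a count of 0 allows, which is why they are given here. In each library 8 of these features were above 0. What the identifiers stand for is not given in the sources used here, and no explanation was tested. Groups of 2 libraries are too small for a test of single libraries that stand apart.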

How the results depend on the processing

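The count of lists without the splicing genes was the 1 alternative chosen after the values were seen. The number of detected genes was 13813 to 18697 over the alternatives, and 15935 and 16016 in single libraries. Hox groups 1 to 5 had 12 to 14 genes detected and groups 6 to 13 had 6 to 10. Forebrain transcription factors moved from 6 detected to 11 at a minimum of 0.5 TPM, and to 7 and 14 without replicate 2 and without replicate 1. Of 280 values for the other 35 lists, 274 stayed within 1.5 times. The exceptions were 5 midbrain genes at 2 TPM and at an FPKM of 1, 3 muscle genes at 2 TPM, and 0 X inactivation, 1 long noncoding and 0 mitochondrial genes over nuclear coding genes, which those lists mostly lack by construction. Lists apart numbered 21 of 35 as reported, 20 of 34 without the splicing genes, 20 of 34 at a mean count of 100 or more, 21 of 36 with no minimum and 21 on TPM ratios. Other scalings move all genes alike and could not change that count. Genes over 2-fold apart, 323 as reported, numbered 326, 323 and 373 under DESeq2 size factors, library totals and spike-in totals, and 274 on TPM with a pseudocount of 0.1. They numbered 60 at a mean count of 100 or more, 4943 with no minimum and 84 on TPM with a pseudocount of 1. The first has fewer genes to count from, no minimum admits genes of few counts, and a pseudocount of 1 shrinks low genes, by construction. The coefficient of variation was 0.0844 for coding genes alone against 0.0892, and 0.0893 and 0.0952 under the other alternatives; the cause was not tested. Leading transcripts that differed numbered 845 of 10400 at 1 TPM, 268 of 5114 at 20 TPM, 541 of 8395 on posterior TPM and 517 of 8177 for coding genes. No paired analysis was possible because there is 1 group.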

Other observations

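Globin genes moved apart between the pools, in a grouping chosen after the values were seen. The 4 adult genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt summed to 15729 TPM in replicate 1 and 12349 TPM in replicate 2, a ratio of counts of 0.766 (0.761 to 0.771). The 3 embryonic genes, which primitive red cells make, went the other way, from 120.1 to 183 TPM and a ratio of 1.49 (1.41 to 1.58). Of the vesicular glutamate transporters, Slc17a6 exceeded Slc17a7 158-fold in replicate 1 and 65.1-fold in replicate 2. Lhx2 and Lhx9, transcription factors of several brain regions and named after their values were seen, had 30.3 ± 28.8 and 31.8 ± 26.8 TPM. Their ratios of replicate 2 over replicate 1 were 0.235 (0.215 to 0.257) and 0.273 (0.257 to 0.291).

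For the patterns weighed here, the tests of counting error and the gradient over Hox genes were chosen only after the result was seen. With 1 group, no biological explanation was tested, and neighbouring tissue in a pool is weighed as a mixed sample. With 1 library per pool, differences between pools and between library preparations are not separable.

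Hox groups 6 to 13 were higher in replicate 2. Against counting error as the whole cause, their summed counts had a bound nearest 1 of 1.72. After a regression on transcript length and GC content, their median of 0.79 stayed at the 100th percentile of matched random lists. That regression explained 1.98% of the variance of the log2 ratio and changed it by a median of 0.0358 in size. A length and GC trend of that size is too small to be the whole cause, and the percentile adds little to that. The same limit holds for the lists below. The log2 ratio also went up with paralogue group, with Spearman's rho of 0.746 over 24 Hox genes, which are not independent, and 0.712 to 0.841 without any 1 gene. Part of that rise restates the pattern itself, since groups 6 to 13 were already known to be higher. Median log2 ratios were 0.12 in groups 1 to 5, 0.35 in groups 6 and 7 and 2.80 in groups 8 and 9. A candidate explanation is that pool 2 held more tissue from behind the hindbrain, a hypothesis found and tested on the same data. It stays open, since with 1 library per pool it has no independent check. Lists for types that tissue behind the hindbrain also holds went both ways. They cannot decide the question, because these types are not confined to that tissue. Cartilage and bone was higher in replicate 2 at 0.28, the value of Sox9, also a radial glia gene. Cholinergic and motor neurons, peripheral nerve and sensory ganglia, and skeletal muscle were lower at -0.44, -0.45 and -0.61. Of cartilage and bone genes 5 of 13 were detected, and of skeletal muscle genes 6 of 14.

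Forebrain transcription factors were also higher in replicate 2. Their summed counts had a bound nearest 1 of 1.44, and after the same regression their median of 0.76 stayed at the 100th percentile, against counting error or a length and GC trend as the whole cause. A second list of 22 striatal and cortical genes, sharing 0 genes with the fixed lists, had a median of 0.16 with 20 higher, at the 100th percentile. That may reflect some forebrain tissue in pool 2, but 21 of the 22 were detected in both libraries, led by Penk at 128 ± 4.29, Tac1 at 115 ± 9.85 and Lmo3 at 67.5 ± 7.25 TPM. Synaptic genes were higher as well, at 0.13, so the test does not separate forebrain tissue from a wider neuronal difference.

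The midbrain list was lower in replicate 2. Its summed counts had a bound nearest 1 of 0.844, and after the regression its median of -0.47 stayed at the 0th percentile, against counting error or a length and GC trend as the whole cause. A second list of 17 midbrain and diencephalon genes, with 0 in the fixed lists, had a median of -0.05 at the 10.0th percentile, outside the 2.5 set for it but below the middle of random lists. Of its genes 16 were detected in both libraries, led by Mab21l2 at 159 ± 16.1, Meis2 at 113 ± 0.141 and Calb2 at 95.2 ± 8.78 TPM. The summed counts of that second list had a ratio of 0.904 (0.893 to 0.916), on the lower side, with 11 genes lower and 6 higher. En1, En2, Lhx2 and Lhx9, also lower in replicate 2, are not in that list and were named after their values were seen. Whether pool 1 held more tissue from in front of the hindbrain or differed otherwise cannot be told apart. The test was set on the median of the second list, which fell between both predictions.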
